A study of Burkholderia glumae BGR1 with 6 samples.

How the data were processed

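RNA was measured by sequencing in 6 libraries of wild-type Burkholderia glumae BGR1, a bacterium that causes grain rot and seedling rot of rice. Per the labels, 3 libraries came from bacteria in culture (in vitro, 6 h) and 3 from bacteria recovered from rice stems (in vivo). A culture temperature of 37 °C is given for all 6, and for the in vivo libraries it need not be the temperature in the stems. Per the labels' protocols, stems of plants at the vegetative stage were injected with a suspension at an optical density of 0.5. Stems with symptoms were collected after 8 days and spun to pellet the bacteria.

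The authors' deposited tables list 6224 genes with their replicon, coordinates, a count of reads and an RPKM value, per the file headers. BWA is named in the submitters' processing notes. The counting tool, its treatment of strand and of reads with several matches, and the mapping settings are not given in the sources used here. The deposited RPKM values (reads per kilobase, scaled by the library total) were recomputed from the counts, the listed length and the sum of the listed counts. Above an RPKM of 10 the largest difference was 0.00491%. The counts were used for every test. Of the gene models, 6138 have a coding length that is a multiple of 3, and which of them encode RNA cannot be read from the tables.

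Total counts were 4760788, 6554389 and 7963283 for in vitro replicates 1, 2 and 3, and 3186594, 3208861 and 3225431 for in vivo replicates 1, 2 and 3. Nothing in the labels says that replicates came from separate cultures or plants, so p-values measure the spread between these samples, which may be technical. Low counts were mostly even. Among counts from 10 to below 200, 29.7% (in vitro replicate 1) to 47.1% (in vitro replicate 3) were odd, as happens when both mates of a read pair are counted. In in vitro replicate 3 the excess of even counts was small. Of the listed genes, 1702 overlap a neighbour, and reads in the overlap can count for both.

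The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) of in vivo against in vitro on the deposited counts, with TMM normalization. The default expression filter kept 5400 genes and removed 824. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. A second count required at least a 2-fold change. The common dispersion was 0.339, a biological coefficient of variation of 58.2%. On simulated counts for this comparison, over 5400 genes, the test recovered 0% of genes changed 2-fold, 6.25% of those changed 4-fold, 57.1% of those changed 8-fold and 98% of those changed 32-fold. Of 83 calls, 3 were false. In the simulation, changes of 2-fold and 4-fold were therefore mostly beyond reach. It changed 49, 48, 49 and 50 genes at these sizes, whereas the data gave 573 calls. With more changed genes the adjusted threshold is less strict, so recovery in the data may be higher. The simulation also drew all libraries with the same dispersion for a gene and had no outlying library. In the data, in vitro replicate 3 stood apart, as described below. The simulated recovery and false calls therefore need not hold for the data.

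The deposited tables give locus identifiers and do not pair them with gene names or products, and no genome or annotation was used here. The 24 gene lists fixed before the data were examined were therefore not evaluated, and no gene is described by function. In their place, neighbouring genes that changed together were described by position. This rule was written after the tables had been opened and showed no names, but before fold changes were computed, so it was not among the choices fixed beforehand. A run is a stretch of consecutive listed genes, all at an adjusted p under 0.05 and at least 2-fold changed in the same direction. A gene that a fit did not test ends a run. The 5 longest runs in each direction were described, with ties broken by the median absolute log2 fold change. Runs of at least 3 genes were tested by permuting gene order within each replicon 10000 times. Single genes were named only among those with an adjusted p under 0.05, a mean log2 CPM of at least 5 and no overlap between the groups' values. Of these, the 2 with the largest rise and the 2 with the largest fall are given. Coordinates are as the deposited tables give them.

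Shares of counts per replicon were compared by two-sided exact permutation tests. The chromosome of changed genes was compared by Fisher's exact test. A rotation of the calls along both chromosomes, which keeps neighbours together, was added after the data were seen. SciPy and pandas were used for these tests, with DESeq2 1.42.0 and limma 3.58.1 for alternatives. The alternatives covered normalization, filters, other tests, a replicate block, each library left out, halved counts, overlapping genes left out and library weights.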

Results

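The transcriptome of Burkholderia glumae BGR1 was measured in 3 libraries from bacteria grown in culture and 3 from bacteria recovered from infected rice stems, to compare expression in vitro with expression in the host plant. The groups differ at once in host, in time (6 h of culture, 8 days in stems) and in recovery from tissue. The temperature given is that of culture, so temperature in the stems may differ too. The effects of these cannot be told apart. The genome has 2 chromosomes and 4 plasmids. Total counts ranged from 3186594 to 3225431 in vivo and from 4760788 to 7963283 in vitro. Chromosome 1 holds 3431 of the 6224 listed genes and chromosome 2 holds 2272.

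The groups separated along the first principal component, which carried 53% of the variance. In vitro replicate 3 stood apart from the other in vitro libraries along the second, which carried 28.1%. Across genes, the Pearson correlation of log CPM was 0.94 between in vitro replicates 1 and 2. It was 0.729 and 0.783 between replicate 3 and these libraries. Within the in vivo group it lay between 0.895 and 0.934. Genes are not independent replicates, so these correlations carry no test.

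**Figure D1:**
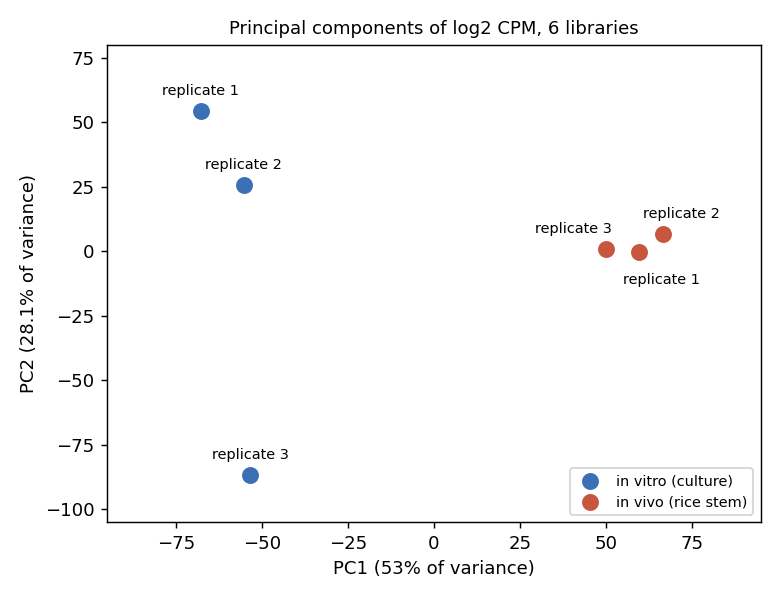
First (53% of variance) and second (28.1%) principal components of log2 CPM, with a point for each library. The 3 in vivo libraries lie close together, and in vitro replicate 3 lies apart from in vitro replicates 1 and 2 on the second component.

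In rice stems, 395 genes were higher and 178 were lower than in culture (edgeR quasi-likelihood test, adjusted p under 0.05, 5400 genes tested). Every called gene changed at least 2-fold. The genes higher in vivo had a median log2 fold change of 3.49, and 150 of them rose at least 16-fold. The genes lower in vivo had a median of -2.32, and 11 fell at least 16-fold. Genes called higher took 1.64% ± 0.0886 (SD, n = 3) of the counts in vitro and 24.7% ± 3.05 (SD, n = 3) in vivo. Genes called lower took 11% ± 2.12 in vitro and 1.61% ± 0.252 in vivo (SD, n = 3 each). These shares describe genes chosen for their change.

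The size of both lists rested on individual libraries and on the test. Without in vitro replicate 3 the counts were 893 and 658, without in vitro replicate 2 they were 154 and 39, and without in vivo replicates 1, 2 or 3 they were 169 and 10, 177 and 13, or 223 and 34. DESeq2 gave 698 and 506.

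Genes that changed lay next to each other more often than in permuted gene orders, though most were outside runs. Of the 395 higher genes, 146 fell in 34 runs of at least 3 neighbours, against a mean of 7.03 in permuted gene orders. Of the 178 lower genes, 32 fell in 8 runs, against a mean of 0.580. Both one-sided permutation p-values were 1.00e-04, the smallest that 10000 permutations can give. Neighbouring genes can share a transcript, and overlapping genes can share reads. With overlapping genes left out, runs held 91 higher and 19 lower genes. Each gene left out ends the run it lies in, so part of this fall is built in. It therefore cannot tell whether shared reads made the runs. That fit called 323 higher and 161 lower genes. Runs of lower genes held 0 genes without in vivo replicate 1 or 2, 4 without in vivo replicate 3, 3 without in vitro replicate 2 and 157 without in vitro replicate 3. Runs of higher genes held 49, 52 and 65 genes without in vivo replicates 1, 2 and 3, 33 without in vitro replicate 2 and 501 without in vitro replicate 3.

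The longest run higher in vivo held 12 genes on chromosome 1, from 1153838 to 1167290. Its genes rose by a median log2 fold change of 6.87 (range 2.91 to 8.08, largest adjusted p 0.0245 by the edgeR quasi-likelihood test). Together they took 243 ± 61.9 CPM in vitro and 42103 ± 13393 CPM in vivo (SD, n = 3 each). Of its genes, 4 overlap another member. On chromosome 2, 8 genes from 1652557 to 1676444 rose by a median of 5.13, from 62.3 ± 17.7 to 2022 ± 726 CPM. All 8 overlap another member, and reads in an overlap can count for both. Also on chromosome 2, 7 genes from 696408 to 706308 rose by a median of 4.71, from 75.3 ± 22.2 to 1410 ± 558 CPM. A run of 6 genes from 887357 to 897269 on chromosome 2 rose by a median of 3.86, from 20.5 ± 7.12 to 332 ± 95.1 CPM. Of its genes, 5 overlap another member. With overlapping genes left out only 1 of its genes was tested, and it was called. On chromosome 1, 6 genes from 1956897 to 1964653 rose by a median of 3.76, from 156 ± 99.2 to 1942 ± 914 CPM. In the first 3 of these regions most genes stayed called under every alternative fit that tested them, the test against a 2-fold change included. That test called 2 of the 6 genes from 1956897. In the 6-gene runs the fewest genes called after leaving out a library were 2 and 1.

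The longest run lower in vivo held 6 genes on plasmid 4, from 108851 to 116368. Its median log2 fold change was -2.41 (range -3.01 to -1.87), and its summed level went from 2021 ± 184 CPM in vitro to 484 ± 58.9 CPM in vivo (SD, n = 3 each). Of its genes, 2 overlap another member. On chromosome 1, 5 genes from 251244 to 255098 had a median of -3.13, from 1664 ± 1048 to 182 ± 70.8 CPM. Another 5 genes on chromosome 1, from 463456 to 468733, had a median of -2.36, from 1591 ± 296 to 265 ± 72.0 CPM. On chromosome 2, 4 genes from 2154442 to 2157932 had a median of -2.47, from 555 ± 109 to 103 ± 32 CPM, and all 4 overlap another member. The last region, 3 genes from 190989 to 192809 on chromosome 2, had a median of -4.04, from 160 ± 36.1 to 5.90 ± 2.48 CPM. After leaving out a library, the fewest genes called in the 5 lower regions were 2, 0, 0, 0 and 1. The test against a 2-fold change called 3, 1, 2, 2 and 2.

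**Figure D2:**
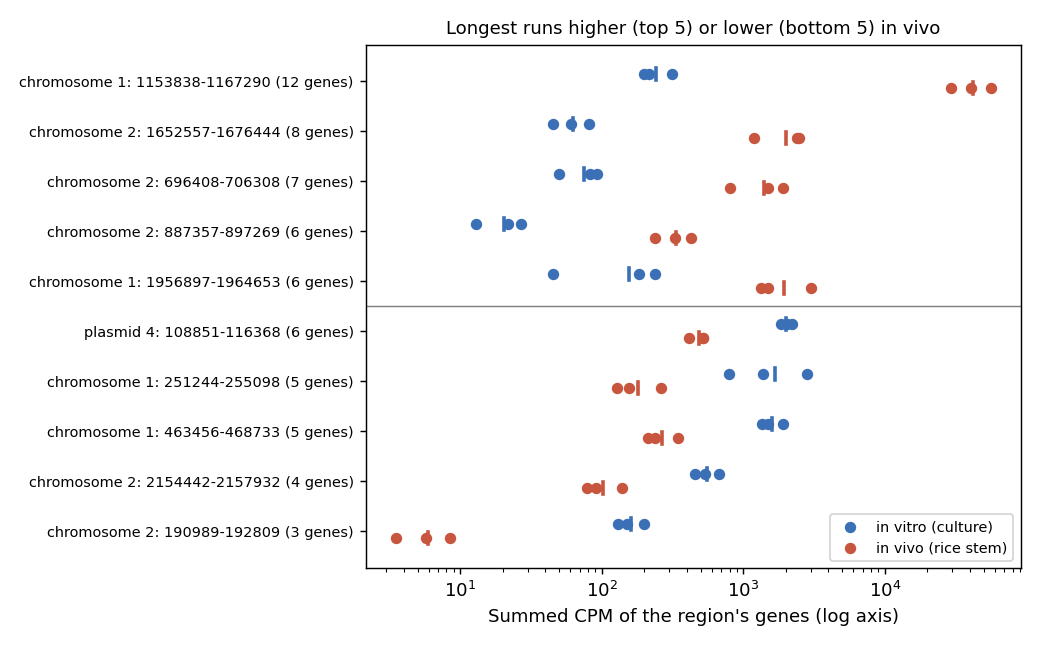
Summed CPM (log axis) of the genes of each region, with a point for each library and a bar at the mean of 3. In the run of 12 genes on chromosome 1 the mean was 243 CPM in vitro and 42103 CPM in vivo.

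Called genes reached log2 fold changes of 8.43 and -7.06, and those named here rank largest among called genes with a mean log2 CPM of at least 5 and no overlap between the groups' values. Within that limit the largest rise was in bglu_1g10650 on chromosome 1, from 1164104 to 1165297, inside the run of 12. It overlaps a neighbour. It had 106 ± 76.6 CPM in vitro and 28757 ± 11501 CPM in vivo (SD, n = 3 each), a log2 fold change of 8.08 ± 0.97 (SE, adjusted p 0.00390, edgeR). Each SE given for a fold change is approximate: the absolute log2 fold change divided by the square root of the test's F value. Gene bglu_2g13790 on chromosome 2, from 1767479 to 1769212, rose from 11.3 ± 5.77 to 2191 ± 1364 CPM, a log2 fold change of 7.60 ± 0.90 (adjusted p 0.00379, edgeR). Within the same limit the largest fall was in bglu_2g01630 on chromosome 2, from 190989 to 191411, inside the lower run of 3 genes. It had 94.9 ± 22.1 CPM in vitro and 1.92 ± 1.07 CPM in vivo. Its log2 fold change was -5.59 ± 0.60 (adjusted p 0.00282, edgeR). Gene bglu_1g00530 on chromosome 1, from 54796 to 55701, had 326 ± 224 CPM in vitro and 11.9 ± 2.46 CPM in vivo, a log2 fold change of -4.77 ± 0.69 (adjusted p 0.00718, edgeR).

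Higher genes were more frequent on chromosome 2. They were 225 of 1965 tested genes there (11.5%) and 155 of 3073 on chromosome 1 (5.04%), an odds ratio of 2.43 (two-sided Fisher's exact p = 1.50e-16). Lower genes were 51 of 1965 on chromosome 2 and 112 of 3073 on chromosome 1, an odds ratio of 0.704 (two-sided Fisher's exact p = 0.0414). Adjusted over these 2 tests, the exact p-values were 3.00e-16 and 0.0414. Fisher's test takes genes as independent. When the calls were rotated along both chromosomes, which keeps neighbours together, the two-sided p was 0.136 for higher and 0.272 for lower genes. The difference between the chromosomes therefore did not pass the threshold once the clustering of calls was kept. The odds ratio of lower genes was 1.24 without in vitro replicate 2 and 1.20 without in vivo replicate 3.

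**Figure D3:**
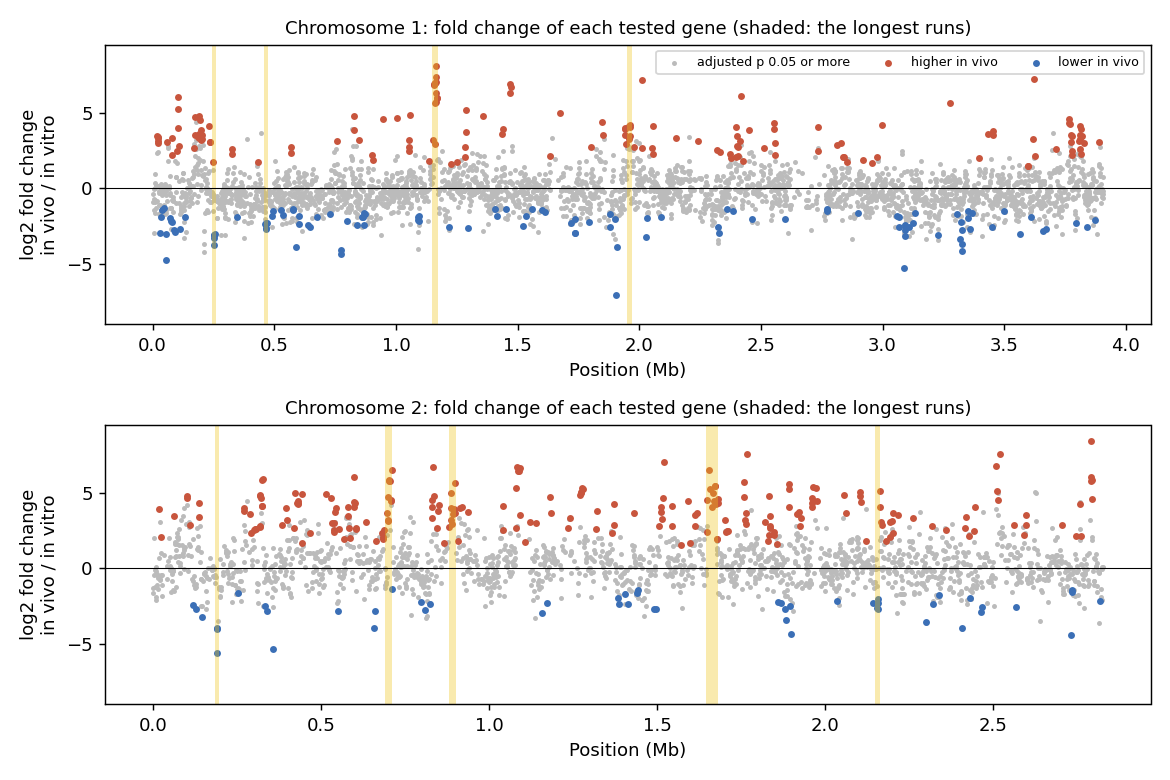
Log2 fold change, in vivo over in vitro, of each tested gene against its position in Mb on chromosomes 1 and 2. Coloured points have an adjusted p under 0.05, and shading marks the regions described; 225 higher genes lie on chromosome 2 and 155 on chromosome 1.

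Plasmid 4 took 1.36% ± 0.141 of the counts in vitro and 0.531% ± 0.0550 in vivo (SD, n = 3 each), and its 86 tested genes included 10 lower and 0 higher (edgeR). The share lower was 11.6%, against 3.30% of all tested genes, and 6 of the 10 form the run described above. At an unadjusted p under 0.05, 25 genes of plasmid 4 were lower and 3 higher, and DESeq2 called 19 lower and 2 higher. Plasmid 1 went from 1.20% ± 0.0858 to 0.816% ± 0.0705, and plasmid 3 from 0.979% ± 0.134 to 0.589% ± 0.0800. Counts listed for plasmid 2 went from 0.104% ± 0.0277 to 0.152% ± 0.0146. Of its 36 genes with counts, 26 had a counterpart on another replicon with the same length, spacing and neighbour length, so the replicon these counts came from is uncertain. For each plasmid the 3 in vivo values lay outside the range of the in vitro values, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows. The adjusted value over the 6 replicons was 0.150. Chromosome 1 took 75.7% ± 4.32 in vitro and 73.1% ± 0.565 in vivo, and chromosome 2 took 20.7% ± 4.51 and 24.8% ± 0.409 (exact p 0.400 for each). In vitro replicate 3, with 25.9% on chromosome 2, lay above every in vivo library. The in vivo minus in vitro difference was -2.63 points for chromosome 1 and 4.18 for chromosome 2. It was -5.11 and 6.78 without in vitro replicate 3, and -1.13 and 2.77 without in vitro replicate 2. Without in vitro replicate 1 it was -1.65 and 2.99. With the 10 genes of highest mean share left out it was -6.22 and 7.76, and for plasmid 2 it went from 0.0482 to 0.0747 points.

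On plasmid 2, 85 of 121 genes had 0 counts in all 6 libraries. Elsewhere this held for 8 of 6103 genes, and for 0 of 400 on the other plasmids. Over the counts of all 6 libraries, 0 counts allow a level of up to 0.104 CPM for a gene, for counting error only. This takes counts as independent, and the bound is higher if both mates of a pair were counted. The longest stretch at 0 held 26 genes, from 93118 to 116753.

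**Figure D4:**
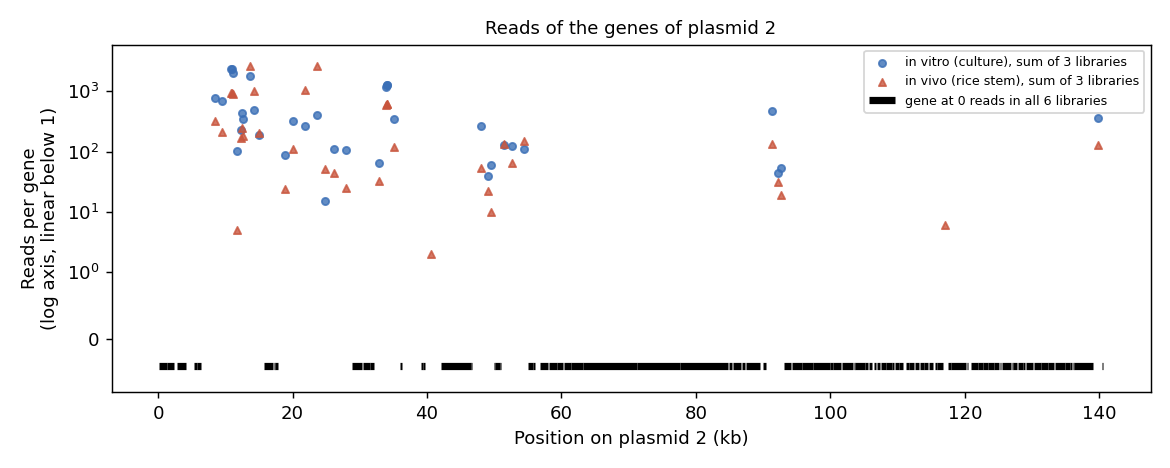
Counts per gene of plasmid 2 against position in kb, summed over the 3 libraries of each group (log axis, linear below 1). Black bars mark the 85 genes at 0 in all 6 libraries.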

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

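Halved counts, overlapping genes left out, library weights, alternatives for runs and regions, those for the chromosome of changed genes except the planned 2-fold minimum, the 2-fold test of single genes and left-out libraries for replicon shares were chosen after the data were seen. The run rule was written after the tables were opened but before fold changes were computed. DESeq2 gave 698 higher and 506 lower genes (505 lower at 2-fold) and 323 and 138 genes in runs. Library weights in limma-voom, which gave in vitro replicate 3 a weight of 0.118, gave 970 and 759 (932 and 609 at 2-fold) and 517 and 192 in runs. A test against a 2-fold change gave 224 and 42. With overlapping genes left out, 91 and 19 genes lay in runs, where each gene left out ends its run. Leaving out a library gave 154 to 893 higher and 10 to 658 lower genes, 154 to 872 and 10 to 558 at 2-fold, and 33 to 501 and 0 to 157 in runs. Fewer samples lower the power, yet leaving out in vitro replicate 3 raised every one of these counts. Total counts and upper quartile scaling moved the median of all genes by -0.16 and -0.13. Voom and the replicate block each moved it by 0.13, library weights by 0.16 and leaving out in vitro replicate 3 by 0.19.

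For lower genes the odds ratio of chromosome 2 against chromosome 1 was 0.870 with the strict filter and 0.727 with halved counts, and ranged from 0.470 to 1.24 when a library was left out. The cause was not tested. For higher genes it kept its direction and, by Fisher's exact test, its side of the threshold under every alternative fit, but the rotation, which keeps neighbours together, gave 0.136. Without the 10 genes of highest share, the in vivo minus in vitro difference was -6.22 points for chromosome 1, 7.76 for chromosome 2 and 0.0747 for plasmid 2. Median fold changes of the 10 regions kept their sign in all 178 region and alternative pairs, and in 33 of these the called genes were no longer the majority. The 4 genes named singly stayed past the threshold in each alternative that tested them.

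With the replicate block, 268 genes were higher and 58 lower (58 at 2-fold), with 89 and 8 in runs and an odds ratio of 0.757 for lower genes. Deviations of samples with the same number correlated at -0.0289, 0.0849 and 0.011, and not every sample correlated best with its own number. The 0.0849 was the highest of all pairs. Deviations from a group mean are tied to each other, so these values cannot exclude a shared day or batch.

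Leaving out ribosomal and transfer RNA genes, and camera and fry tests of the lists, were not run because the tables hold no names. Alternatives for normalized values did not apply because counts were deposited.

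The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 395 higher and 178 lower genes, the same at 2-fold, and 178 genes in runs of either direction, and the highest other split gave 0 for each (edgeR, the only tool run on the splits). At an unadjusted p under 0.05 the real split had 1554 genes and the others 35 to 235. In each of these, 1 of 10 splits was as large.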

Other observations

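The tests of gene length, of a swap, of plasmid 2 against other plasmids, of repeated genes, of recurring neighbours and of a silent plasmid were chosen after the result was seen, and so were the comparison with control genes and the rotations.

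Several blocks of genes in in vitro replicate 3 were at the level of the in vivo libraries or above. Those given were chosen as the longest runs of genes more than 4-fold higher in that library than in the mean of in vitro replicates 1 and 2. The 7 genes of chromosome 2 from 769152 to 775188 took 76.5 and 148 summed CPM in in vitro replicates 1 and 2, and 38728 in replicate 3. The in vivo libraries had 7099, 3859 and 14875. The 10 genes from 1241210 to 1267603 on chromosome 2 took 331, 452 and 20699 CPM in vitro and 5460, 10001 and 11268 in vivo. On chromosome 1, 13 genes from 2515107 to 2542559 took 96.0, 96.0 and 1029 CPM in vitro and 591, 667 and 579 in vivo. None of these genes was called with all 6 libraries (edgeR). In the blocks of 7, 10 and 13 genes, 0, 0 and 1 had an unadjusted p under 0.05, and DESeq2 called 0, 0 and 1. Without in vitro replicate 3, 7 of 7, 10 of 10 and 10 of 13 were called higher in vivo, against 893 of all 5389 genes tested in that fit. The way the blocks were chosen largely sets this contrast between the fits, so it is no separate support.

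In vitro replicate 3 differed more than 4-fold from the mean of the other in vitro libraries in 1183 genes. Thinned to the depth of replicate 1, the higher of its correlations with in vitro replicates 1 and 2 was 0.789. Random thinning keeps the expected shares of the counts and only adds noise, so it could hardly raise a correlation. It therefore cannot decide whether depth was the source. A trend on coding length left 88.2% of these genes more than 4-fold apart, so length is unlikely as the whole cause. A swap is argued against, since the highest correlation of in vitro replicate 3 with an in vivo library was 0.675, below the 0.729 with replicate 1. A separate batch and a culture at another growth stage stay open and were not tested: the labels give no batch, but this library's record number lies apart from the consecutive numbers of the other libraries.

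Plasmid 2 had 70.2% of its genes at 0, which argues against low depth as on the other plasmids, and 0 of 242 genes with a recurring length, spacing and neighbour were at 0, which argues against discarding of reads from copied genes. A bound set before, that 90% of the genes at 0 have a gene of the same length elsewhere, was met at 91.8%, but 94.9% of other genes meet it too, so it decides nothing. Absence of most of the plasmid may explain the pattern: 72.2% of its genes with reads had a same-length gene on another replicon with counts within 25%, past a bound of 50% set before. That bound was also met by 54.2% of control genes, but a recurring length, spacing and neighbour was found for 26 of the 36 genes with reads, 0 of the 85 at 0 (two-sided Fisher's exact p = 1.31e-18, genes taken as independent) and 3.54% of genes elsewhere, while 10 of 95 plasmid genes without one had reads, 6 of them with no same-length gene on another replicon with counts within 25%. A silent plasmid stays open too, though the quietest other stretch of 26 genes had 21 with reads, so absence and silence cannot be told apart.

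Tested genes of chromosome 2 had a median log2 fold change 0.578 above those of chromosome 1. The difference was above 0 in all 5 bins of mean expression, with 0.372 as the smallest, and was 0.636 without in vitro replicate 3, which argues against expression level and that library as the whole cause. Gene dosage stays open. Along chromosome 1 the fold change had a Spearman rho of 0.0756 with distance from position 1. The one-sided circular shift p of 0.116 lies between the bounds set before, and on chromosome 2 rho was 0.0769 (p 0.207). Position 1 was assumed to be the replication origin, so these values bear on dosage only if that holds. Rotating the fold changes along both chromosomes gave a two-sided p of 0.0383 for the difference of medians, or 0.115 adjusted over the 3 rotation tests, which does not pass the threshold. A regulatory response to the plant was not tested.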
